A study of Homo sapiens with 34 samples.

How the data were processed

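Gene expression was measured in 34 arrays of H9 human embryonic stem cells, a line derived from the inner cell mass of a blastocyst, after 24 h of exposure. RNA was hybridised to Illumina human bead arrays. The labels place the arrays in 14 groups of 2 to 4 and name each by its medium (HES, CM or KSR), its treatment and a replicate number. They do not expand the medium codes, give no dose and do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

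The authors deposited log2 intensities, with 1 value per probe and array. Per the submitters' processing notes, limma was used; its version, the background correction and any probe filter are not given in the sources used here. The deposited log2 values shared 1 distribution: the medians of the arrays differed by at most 0.000709 and the 90th percentiles by at most 0.00149, which is the state that quantile normalization leaves. They were therefore used as they stood, with no further normalization. The median of the arrays was 6.62, the 10th percentile 5.89 and the 90th percentile 10.43. No detection p-value per probe was used here, so it could not be judged which probes lay above background, and changes of dim genes are understated where background was left in. The number of arrays limits the precision: the median standard error of a log2 change was 0.123 for 2 arrays against 3 and 0.135 for 2 against 2.

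Of 22185 probes, 44 had no value and 22141 were tested. Probes were named through the platform annotation and the RefSeq gene table: 19677 probes had 1 gene symbol, 0 had several and 2464 had none and stayed unnamed. Each of 16564 genes was represented by its probe with the highest mean over all arrays; 2256 genes had more than 1 probe. No genome build was used, and no positions are given.

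Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per group over all 34 arrays, so that groups of 2 shared an estimate of the spread with 20 residual degrees of freedom. The 15 comparisons were each adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05, and every adjusted p of a gene below comes from this fit. RA, CYM and SRM were set against the KSR control, and SLG against DMSO. Whether RA, CYM and SRM were given in DMSO is not stated in the labels. Changes are log2 differences of group means, given with the standard error of the fit.

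Gene lists (38, of signalling targets, stress responses, metabolism, cell cycle and cell types) were tested with camera from limma, over 1 probe per gene, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, each adjusted by Benjamini-Hochberg over the lists of a comparison. Members of a list were counted at the threshold over all probes and again adjusted over the list alone. The list called amino acid stress below holds genes of the transcription factor ATF4 and the integrated stress response. Its name does not state which stress acted. The groups, comparisons, lists, tests, alternative settings and the rule for naming genes were chosen before the data were examined. By that rule, each comparison names up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold whose treated arrays all lay on 1 side of the control mean, up to 4 members of a list with the smallest p, and POU5F1, NANOG and SOX2 throughout. Uncharacterised names are left out.

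Correlations of log2 changes between comparisons are across genes, which are not independent replicates. Where both share control arrays, the value that 20 simulations of unchanged groups gave is printed beside them.

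The replicate numbers were checked for pairing by correlating, across genes, the deviations of equally numbered arrays from their group means. For FGF2 in CM medium these correlations were 0.34 to 0.472 over 3 pairs and for the KSR against the HES control 0.108 to 0.402, all above 0.1, so the numbers pair the arrays there, by the data and not by a label. For FGF2 in HES medium they were -0.126 to 0.179 and for the CM against the HES control -0.0386 to 0.208, and the other comparisons held 2 pairs.

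The fit was tested on simulated data with the spread of these arrays, with 200 of 22141 probes changed. For FGF2 in HES medium 62.8% of probes changed by 0.5 (log2) and 99.8% of those changed by 1 were called; for THEA the shares were 46.6% and 97.8%, and for SLG 35% and 94.6%. For RA they were 53.8% and 97.4%. False calls made up 4.52% to 7% of the calls, the largest share for SLG. Each simulated probe had the same spread in all groups. In the data the DMSO arrays differed from each other by an SD of 0.316 over probes and the THEA arrays by 0.179. The shares for SLG may therefore not describe that comparison. In 20 simulations over 16564 genes camera found the 1 list of 20 genes shifted by 0.3 in 100% of runs and called 1 other list in all. All simulated genes varied independently and the lists were random. The simulations therefore cannot show how the preset test behaves for lists whose members vary together. With an estimated correlation 10 list calls in the data were kept and 78 lost.

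Alternatives tried were the replicate number as a block, a filter on dim probes, quantile normalization again, centring on medians, a trended and robust eBayes, a fit of the compared groups only, array weights, a 2-fold minimum, other KSR controls and leaving out each array. An intensity floor planned for linear values was not needed, since the values are log2. Figures were drawn with matplotlib 3.10.9.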

Results

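Undifferentiated H9 cells were exposed for 24 h to a growth factor, a vehicle or a small molecule, and their RNA was measured on 34 arrays. The series describes its compounds as promoting self-renewal or differentiation. In HES medium the groups were the control (n = 3), FGF2 (n = 3), THEA, FBP, SNM and GTFX (n = 2 each). In CM medium they were the control (n = 3) and FGF2 (n = 4), and in KSR medium the control (n = 3), RA, CYM, SRM, DMSO and SLG (n = 2 each). The published screen behind this series names retinoic acid, cymarin, sarmentogenin, selegiline, theanine, flurbiprofen, sinomenine and gatifloxacin, while the labels give only the codes. Arrays of 1 group correlated at 0.985 to 0.996 over all probes, and no pair held identical values.

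The transcription factor genes POU5F1, NANOG and SOX2, which sustain pluripotency, passed the threshold in none of the 15 comparisons. Under RA, POU5F1 was 13.77 ± 0.07 (SD, n = 2) against 13.98 ± 0.07 (SD, n = 3) in the KSR control, a log2 difference of -0.22 ± 0.12 with adjusted p = 0.54. NANOG differed by -0.44 ± 0.17 under RA, -0.0393 ± 0.17 under CYM and 0.14 ± 0.17 under SRM. SOX2, whose probe lay below the median level of the arrays, differed by 0.0547 ± 0.12, -0.0753 ± 0.12 and 0.0594 ± 0.12 in the same order. That probe read 6.16 to 6.47 in the RA and KSR control arrays, close to the 25th percentile of 6.09. A change of SOX2 may therefore go unseen in every comparison. Probes of POU5F1 and NANOG can also read their pseudogenes, and a p above the threshold does not show that levels were equal.

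**Figure D1:**
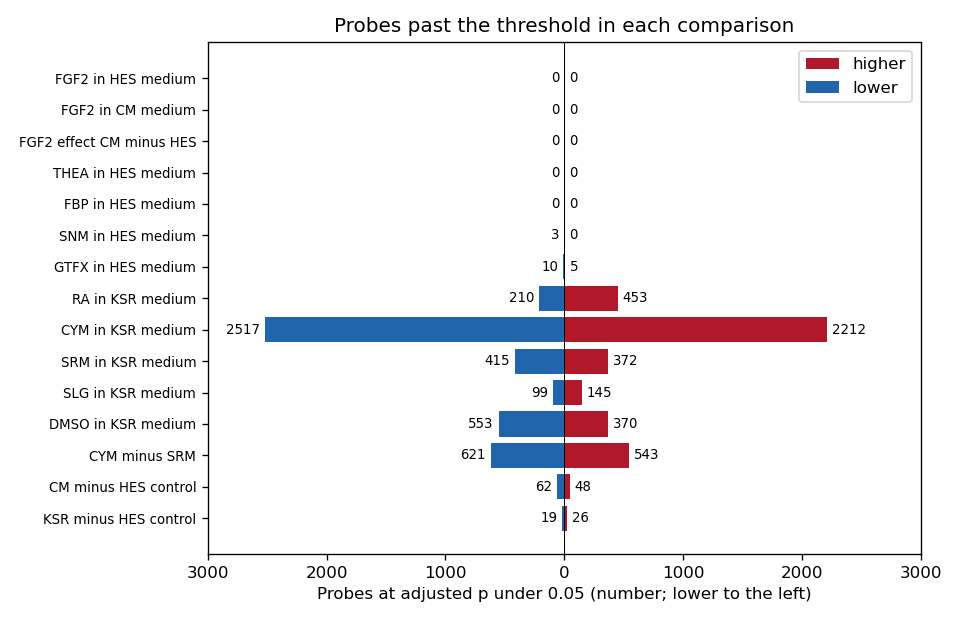
Bars give the number of probes past an adjusted p of 0.05 (limma, Benjamini-Hochberg) in each of the 15 comparisons, higher to the right and lower to the left. CYM has 2212 higher and 2517 lower probes, and the FGF2, THEA and FBP comparisons have 0.

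FGF2, a growth factor used to keep human embryonic stem cells undifferentiated, was compared with the control in HES medium. No gene passed the threshold. SPRED2, an inhibitor of ERK signalling, differed by 0.20 ± 0.14 and PHLDA1 by -0.38 ± 0.29. Of 22 measured FGF and ERK target genes 0 rose and 0 fell, with 0 higher and 0 lower when adjusted over the list alone. POU5F1 differed by -0.0191 ± 0.11, NANOG by -0.0507 ± 0.15 and SOX2 by 0.18 ± 0.11. Limma called 0 of 22141 probes. An unadjusted p under 0.05 was seen in 530 (2.39%). That is a smaller share than the 0.05 that unchanged probes would give, so it is no sign of an effect. Here and below, so low a share is not evidence against an effect either. The spread is shared over all groups, and the arrays of some groups differed more, which makes the test cautious where arrays were alike.

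FGF2 was also compared with the control in CM medium. The ERK phosphatase genes DUSP5 and DUSP6 differed by 0.62 ± 0.23 and 0.34 ± 0.14, the BMP target gene ID3 by 0.66 ± 0.16, and the mesendoderm regulator genes EOMES and GSC by 0.69 ± 0.21 and 0.34 ± 0.09. None of these passed over all probes. FGF and ERK targets (22 measured, 0 higher and 0 lower when adjusted over the list alone) were shifted as a list (mean 0.15, camera adjusted p = 0.00193, and adjusted p = 0.437 with an estimated correlation). Mesendoderm genes (17 measured, 2 higher and 0 lower when adjusted over the list alone) were shifted as well (mean 0.18, camera adjusted p = 0.000875, and adjusted p = 0.146 with an estimated correlation). BMP, Wnt, amino acid stress, NRF2, endoderm, fibroblast-like and epithelial or mesenchymal genes also passed the preset test, with 0 members called over all probes. When adjusted over the list alone, 1 BMP target, 1 Wnt target, 1 NRF2 target and 2 amino acid stress genes were higher. Their adjusted p was 0.28 to 0.645 with an estimated correlation. POU5F1 differed by 0.00765 ± 0.10, NANOG by -0.0504 ± 0.14 and SOX2 by -0.0382 ± 0.10.

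In the same comparison FGF2 array 4 stood apart from the other 3 arrays of its group, by 0.76 for fibroblast-like, 0.70 for endoderm, 0.49 for trophoblast and -0.32 for pluripotency genes. Without it, mesendoderm genes had a mean of 0.10 and a camera adjusted p of 0.06, and FGF and ERK targets 0.0759 and 0.449; the other lists had an adjusted p of 0.567 to 0.973, with a mean of -0.000617 for epithelial or mesenchymal genes. Without CM control array 3, FGF and ERK, BMP, Wnt, endoderm and epithelial or mesenchymal genes had 0.111, 0.0596, 0.399, 0.0997 and 0.114. Amino acid stress genes had 0.0976 without CM control array 2, and epithelial or mesenchymal genes 0.285 without CM control array 1. With the replicate number as a block, which leaves no partner for array 4, mesendoderm genes kept the call (adjusted p = 0.0365) and the other 8 lists had 0.509 to 0.952. Limma called 0 probes, with 622 (2.81%) at an unadjusted p under 0.05, again a smaller share than unchanged probes would give. This fit leaves out the pairing by replicate number, which can also lower the share. With the block the count was 0 as well.

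The FGF2 difference was then compared between the media. The chemokine receptor gene CXCR4 differed by 0.70 ± 0.32 and the cystine transporter gene SLC7A11 by 0.55 ± 0.18 between CM and HES medium, and neither passed the threshold. NRF2 targets (12 measured, 0 called, 0 higher and 0 lower when adjusted over the list alone) were shifted as a list (mean 0.22, camera adjusted p = 0.0021, and adjusted p = 0.677 with an estimated correlation), as were endoderm genes (16 measured, 0 called, 0 higher and 0 lower when adjusted over the list alone; mean 0.28, camera adjusted p = 0.0138, and adjusted p = 0.677 with an estimated correlation). POU5F1 differed by 0.0267 ± 0.15, NANOG by 0.000314 ± 0.21 and SOX2 by -0.22 ± 0.15. Limma called 0 probes, with 624 (2.82%) at an unadjusted p under 0.05, a smaller share than unchanged probes would give. Without CM_FGF2 array 4 the lists had adjusted p = 0.131 and 0.575, and with the replicate number as a block 0.165 and 0.594.

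THEA and FBP, of the self-renewal set, were compared with the HES control. Under THEA the pluripotency genes UTF1 and GAL differed by -0.37 ± 0.15 and -0.38 ± 0.19, and under FBP UTF1 and PODXL differed by -0.43 ± 0.15 and -0.25 ± 0.17, none past the threshold. Of 30 measured pluripotency genes 0 passed in either comparison, also when adjusted over the list alone. POU5F1, NANOG and SOX2 differed by -0.12 ± 0.12, -0.21 ± 0.17 and 0.0921 ± 0.12 under THEA and by -0.11 ± 0.12, -0.14 ± 0.17 and 0.17 ± 0.12 under FBP. Limma called 0 probes under THEA, with 757 (3.42%) at an unadjusted p under 0.05, and 0 under FBP, with 559 (2.52%). Both shares were smaller than unchanged probes would give.

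SNM, also of the self-renewal set, was compared with the same control. The membrane protein gene STOM fell by 0.87 ± 0.13 (adjusted p = 0.00505), STXBP6 fell by 0.72 ± 0.13 and the apolipoprotein gene APOC1 fell by 0.61 ± 0.10. These were the 3 probes limma called, beside 0 higher. Amino acid stress genes (19 measured, 0 called, 0 higher and 0 lower when adjusted over the list alone) were shifted as a list (mean 0.17, camera adjusted p = 0.0202, and adjusted p = 0.984 with an estimated correlation). POU5F1, NANOG and SOX2 differed by 0.0935 ± 0.12, -0.33 ± 0.17 and -0.0692 ± 0.12. The calls were lost, with their adjusted p, for STOM, APOC1 and STXBP6 without HES control array 1 (0.0827, 0.18 and 0.535), STOM, APOC1 and STXBP6 without SNM array 2 (0.453, 0.537 and 0.83) and STXBP6 without HES control array 3 (0.138). The count was 0 without SNM array 2, 0 without HES control array 1 and 319 without SNM array 1. The list's adjusted p was 0.0658 without HES control array 1, 0.2 without HES control array 3 and 0.675 without SNM array 1.

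GTFX was compared with the HES control. The collagen prolyl hydroxylase gene P4HA2 rose by 0.75 ± 0.10 (adjusted p = 0.000747), the endoplasmic reticulum retrieval receptor gene KDELR3 by 0.69 ± 0.11 and TMEM263 by 0.63 ± 0.09. SCGB3A2 fell by 1.09 ± 0.19, TNFAIP6 fell by 1.06 ± 0.19, the lipoprotein lipase gene LPL fell by 0.82 ± 0.15 and STOM fell by 0.76 ± 0.13. All 19 measured p53 target genes lay above the control, 0 were called over all probes and 3 were higher when adjusted over the list alone (mean 0.32, camera adjusted p = 5.99e-09, and adjusted p = 0.0641 with an estimated correlation). SESN1 differed by 0.59 ± 0.13, XPC by 0.51 ± 0.14 and the cell cycle inhibitor gene CDKN1A by 0.81 ± 0.27. Replication histone genes (14 measured, 0 called, 0 higher and 0 lower when adjusted over the list alone) were lower as a list (mean -0.17, camera adjusted p = 0.00234, and adjusted p = 0.276 with an estimated correlation). POU5F1, NANOG and SOX2 differed by 0.0132 ± 0.12, -0.26 ± 0.17 and -0.0599 ± 0.12. In all 5 probes were higher and 10 lower.

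The GTFX count rested on single arrays. Limma called 1 without GTFX array 2, 158 without GTFX array 1 and 7 without HES control array 1, and 1 of the 14 named genes kept the call without each array in turn. Lost, with the adjusted p, were TMEM263, P4HA2, KDELR3, STOM, TNFAIP6, LPL and SCGB3A2 without GTFX array 2 (0.111 to 0.701), STOM, TNFAIP6, LPL and SCGB3A2 without HES control array 1 (0.089 to 0.106), LPL without HES control array 2 (0.0676) and TNFAIP6 without HES control array 3 (0.114). The histone list had adjusted p = 0.0695 without HES control array 1 and 0.167 without GTFX array 1. With the compared groups alone in the fit, both the SNM and the GTFX count were 0.

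The profiles of the HES compounds were set against FGF2 in CM medium, which shares no array with them. Across 16564 genes the correlation was -0.175 for THEA, -0.00252 for FBP, 0.00213 for SNM and -0.0376 for GTFX, with jackknife standard errors of 0.116 to 0.157. SNM and GTFX correlated at 0.609 with each other, against 0.4 in simulations of unchanged groups with the same controls, and the covariance was 0.0162 against 0.00816. THEA and FBP correlated at 0.628, also against 0.4, with a covariance of 0.00953 against 0.0081. The remaining pairs of these compounds lay below 0.4, at 0.0842 to 0.295. These simulations leave out that array 2 minus array 1 correlated at 0.673 across genes between SNM and GTFX.

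RA, the vitamin A derivative that activates nuclear retinoic acid receptors, was compared with the KSR control. The homeobox gene MEIS2 rose by 4.14 ± 0.14 (17.6-fold), from 5.92 ± 0.02 (SD, n = 3) to 10.06 ± 0.40 (SD, n = 2), with adjusted p = 4.32e-19. Its control level lay near the 10th percentile of the arrays (5.89), so the fold may be understated. SKAP2 rose by 3.20 ± 0.10, the retinoic acid receptor gene RARB by 3.11 ± 0.18 and CYP26A1, whose enzyme degrades retinoic acid, by 3.09 ± 0.34. CYP26A1 had 2 other probes, of which 1 passed in the same direction. Its representative probe read 14.62 and 14.42 in the RA arrays, close to their maximum of 14.75, so its rise may be understated. ZNF503 rose by 4.84 ± 0.19 and TFAP2A by 4.27 ± 0.39. The hyaluronan synthase gene HAS2 rose by 4.10 ± 0.20 and CEBPD by 2.63 ± 0.12. Of 22 measured retinoic acid targets 9 rose and 1 fell, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 9.92e-14, and adjusted p = 0.00206 with an estimated correlation).

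BMP target genes rose with RA. Of 16 measured, 10 rose and 1 fell, with 10 higher and 1 lower when adjusted over the list alone (mean 0.94, camera adjusted p = 3.97e-18, and adjusted p = 2.88e-05 with an estimated correlation). DLX5 rose by 3.46 ± 0.30, ID4 by 1.82 ± 0.18, ID1 by 1.77 ± 0.19 and SMAD6 by 1.67 ± 0.19. Among 20 trophoblast markers 5 rose and 0 fell, with 6 higher and 0 lower when adjusted over the list alone (camera adjusted p = 9.23e-06, and adjusted p = 0.0488 with an estimated correlation). Of these CDX2 rose by 1.31 ± 0.12, GATA2 by 0.74 ± 0.10 and GATA3 by 1.02 ± 0.20. Among 29 HOX genes 3 rose and 0 fell, with 3 higher and 0 lower when adjusted over the list alone. HOXB2 rose by 3.19 ± 0.12, HOXD1 by 0.98 ± 0.12 and HOXA2 by 0.64 ± 0.14. As means over all arrays, the levels of only 3 of 29 HOX genes lay above the median of the arrays. A filter on that level can drop genes raised in the RA arrays alone, so it does not test the rise of such members. HOXA2 lost its call without RA array 2 (0.102). The HOX list passed the preset test (mean 0.18, camera adjusted p = 0.0357, and adjusted p = 0.145 with an estimated correlation), had adjusted p = 0.0936 without RA array 2 and 0.0716 without KSR control array 3, 0.192 with DMSO as the control, and a mean of -0.0384 over members above the median level.

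Genes of lipid synthesis rose with RA. Of 20 cholesterol synthesis genes 10 rose and 0 fell, with 15 higher and 0 lower when adjusted over the list alone (mean 0.52, camera adjusted p = 1.81e-16, and adjusted p = 0.000928 with an estimated correlation). INSIG1, which holds back sterol synthesis, rose by 1.16 ± 0.15, SC5D by 1.11 ± 0.20, LSS by 0.92 ± 0.15 and DHCR7 by 0.85 ± 0.13; SC5D lost its call without RA array 1 (0.0973). Of 11 fatty acid synthesis genes 5 rose and 0 fell, with 9 higher and 0 lower when adjusted over the list alone (mean 0.57, camera adjusted p = 3.03e-12, and adjusted p = 0.00189 with an estimated correlation). ACSS2 rose by 1.34 ± 0.11 and ELOVL6 by 1.08 ± 0.14.

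The Wnt antagonist genes SFRP1 and SFRP2 changed with RA, SFRP1 by -2.04 ± 0.20 and SFRP2 by -1.88 ± 0.22. The forebrain regulator genes ZIC2 and OTX2 changed by -1.67 ± 0.14 and -1.51 ± 0.24, and LRAT, whose enzyme esterifies retinol, by -1.61 ± 0.20. Among 22 FGF and ERK targets 2 rose and 4 fell, with 2 higher and 7 lower when adjusted over the list alone (mean -0.30, camera adjusted p = 0.00262, and adjusted p = 0.445 with an estimated correlation). SPRED2 rose by 1.65 ± 0.16, MYC fell by 1.15 ± 0.21 and DUSP5 fell by 1.37 ± 0.28. Without RA array 2 that list had adjusted p = 0.529. Among 30 pluripotency genes 1 rose and 1 fell, with 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.722), and LEFTY2 rose by 2.06 ± 0.51. In all 453 probes were higher and 210 lower, and 119 genes rose and 37 fell at least 2-fold. Limma called 323 probes without RA array 2, and 44 of 73 named genes kept the call without each array in turn. Among the losses, with their adjusted p, were LEFTY2, DUSP5 and MYC without RA array 2 (0.0943, 0.157 and 0.225), LEFTY2 without KSR control array 1 (0.112) and LEFTY2 without RA array 1 (0.195). Limma called 1761 with DMSO in place of the KSR control, which held 453 of the 663 calls made against the KSR control.

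**Figure D2:**
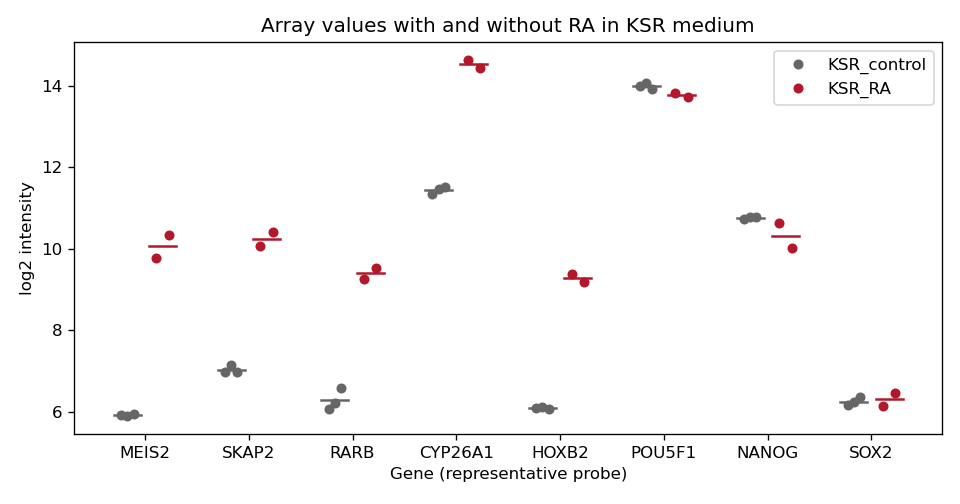
Points are single arrays and lines group means of log2 intensity, for the KSR control (n = 3) and RA (n = 2). MEIS2 rose by 4.14 ± 0.14 and SKAP2 by 3.20 ± 0.10, while POU5F1 differed by -0.22 ± 0.12, which did not pass the test.

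CYM was compared with the KSR control. Cymarin is a cardenolide, a steroid that inhibits the sodium and potassium pump. GDF15, a secreted stress cytokine gene, rose by 3.25 ± 0.24 (9.5-fold, adjusted p = 1.02e-10), DDIT3, a transcription factor gene of the integrated stress response, by 2.81 ± 0.24 and the metallothionein gene MT1H by 3.05 ± 0.40. The chemokine gene CXCL1 rose by 2.54 ± 0.13, the nitric oxide synthase gene NOS3 by 2.48 ± 0.18, TAC1 by 2.47 ± 0.27 and TWIST1 by 2.40 ± 0.51. The pituitary regulator gene HESX1 fell by 2.61 ± 0.25, SFRP1 fell by 2.23 ± 0.20 and CGNL1 fell by 2.12 ± 0.20. In all 2212 probes were higher and 2517 lower, and 272 genes rose and 229 fell at least 2-fold. Limma called 2580 without CYM array 1, and 97 of 130 named genes kept the call without each array in turn.

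Heat shock genes fell with CYM. Of 13 measured, 12 fell and 0 rose, with 0 higher and 12 lower when adjusted over the list alone (mean -1.07, camera adjusted p = 2.37e-12, and adjusted p = 0.00841 with an estimated correlation). HSPA1B fell by 2.03 ± 0.23, HSPA1A fell by 2.01 ± 0.21, HSPA8 fell by 2.0 ± 0.14 and HSPH1 fell by 1.45 ± 0.11. Probes of HSPA1A and HSPA1B can read both of these near-identical genes. Genes of the unfolded protein response of the endoplasmic reticulum moved both ways, 3 higher and 7 lower of 15. When adjusted over the list alone 4 were higher and 7 lower. As a list they had a camera adjusted p of 0.072. SDF2L1 fell by 1.36 ± 0.12 and PDIA4 fell by 1.10 ± 0.11, while HERPUD1 rose by 1.19 ± 0.13.

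Of 19 amino acid stress genes 15 rose with CYM and 0 fell, with 16 higher and 0 lower when adjusted over the list alone (mean 0.96, camera adjusted p = 2.37e-12, and adjusted p = 0.0816 with an estimated correlation). The cystathionine lyase gene CTH rose by 1.16 ± 0.14 and STC2 by 1.61 ± 0.17. Of 19 p53 targets 13 rose and 2 fell, with 13 higher and 2 lower when adjusted over the list alone (mean 0.73, camera adjusted p = 1.8e-06, and adjusted p = 0.0816 with an estimated correlation). Among them GADD45A rose by 2.25 ± 0.21 and ZMAT3 by 1.48 ± 0.20. Of 9 metallothionein and zinc export genes 7 rose and 0 fell, with 7 higher and 0 lower when adjusted over the list alone (mean 1.55, camera adjusted p = 2.76e-05, and adjusted p = 0.0837 with an estimated correlation), and the zinc transporter gene SLC30A1 rose by 1.51 ± 0.18. Of 13 inflammatory genes 4 rose and 0 fell, with 5 higher and 0 lower when adjusted over the list alone (mean 0.57, camera adjusted p = 0.00747, and adjusted p = 0.0816 with an estimated correlation), and CXCL8 rose by 2.03 ± 0.18. Of 15 hypoxia genes 8 rose and 0 fell, with 8 higher and 0 lower when adjusted over the list alone (mean 0.39, camera adjusted p = 0.00747, and adjusted p = 0.133 with an estimated correlation), and P4HA1 rose by 0.93 ± 0.13. With DMSO as the control the mean of the hypoxia genes was 0.20 (adjusted p = 0.237) and that of the inflammatory genes 0.51 (0.156).

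Lists of lipid synthesis, the G1 to S transition and pluripotency were lower with CYM than in the KSR control at the preset correlation. Of 20 cholesterol synthesis genes 12 fell and 1 rose, with 1 higher and 13 lower when adjusted over the list alone (mean -0.42, camera adjusted p = 4.39e-05, and adjusted p = 0.0837 with an estimated correlation). HMGCS1 fell by 1.14 ± 0.12 and NSDHL fell by 1.05 ± 0.12. Of 11 fatty acid synthesis genes 6 fell and 1 rose, with 1 higher and 7 lower when adjusted over the list alone (mean -0.36, camera adjusted p = 0.0158, and adjusted p = 0.319 with an estimated correlation), and the list had adjusted p = 0.145 without CYM array 1. Of 22 genes of the G1 to S transition 11 fell and 2 rose, with 2 higher and 13 lower when adjusted over the list alone (mean -0.34, camera adjusted p = 0.00155, and adjusted p = 0.0911 with an estimated correlation). Genes of G2 and mitosis, 6 higher and 3 lower of 25 with 6 higher and 3 lower when adjusted over the list alone, did not pass as a list (mean 0.0313, camera adjusted p = 0.625). CCNE1 fell by 1.15 ± 0.14 and MCM4 fell by 0.90 ± 0.15. Of 30 pluripotency genes 10 fell and 1 rose, with 1 higher and 10 lower when adjusted over the list alone (mean -0.45, camera adjusted p = 0.00583, and adjusted p = 0.508 with an estimated correlation). With DMSO as the control that mean was 0.00534 (adjusted p = 0.869). In the same arrays fibroblast-like genes had a mean of 0.37 (5 rose and 1 fell of 17), endoderm genes 0.33 (4 and 1 of 16) and neural crest genes 0.23 (3 and 2 of 14), with the same counts when adjusted over the list alone and none of these 3 lists passed. The DNA methyltransferase gene DNMT3B fell by 2.17 ± 0.25 and the telomere protein gene TERF1 fell by 2.05 ± 0.26, while POU5F1 differed by 0.20 ± 0.12. Among 9 measured pump genes 2 rose and 1 fell, with 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.614). ATP1B1 rose by 0.68 ± 0.13 and FXYD5 by 0.64 ± 0.14, a call FXYD5 lost without CYM array 1 (0.0569), and the catalytic subunits were not analysed here.

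SRM was compared with the KSR control, and sarmentogenin is also a cardenolide. GDF15 rose by 2.0 ± 0.24 (adjusted p = 9.09e-06), TAC1 by 1.98 ± 0.27, TXNIP by 1.73 ± 0.23, DDIT3 by 1.65 ± 0.24 and TRIB3 by 1.30 ± 0.24. HESX1 fell by 1.20 ± 0.25, the translation factor gene EIF5 fell by 1.02 ± 0.13 and SFRP1 fell by 1.0 ± 0.20. Of 19 amino acid stress genes 10 rose and 0 fell, with 12 higher and 0 lower when adjusted over the list alone (mean 0.62, camera adjusted p = 2.8e-15, and adjusted p = 0.044 with an estimated correlation). CTH rose by 1.08 ± 0.14. Of 15 hypoxia genes 3 rose and 0 fell, with 6 higher and 0 lower when adjusted over the list alone (mean 0.32, camera adjusted p = 2.26e-05, and adjusted p = 0.044 with an estimated correlation). The hypoxia mean with DMSO as the control was 0.13 (adjusted p = 0.204). P4HA1 rose by 0.71 ± 0.13 and DDIT4 by 0.90 ± 0.18. Calls lost, with their adjusted p, were those of TRIB3, P4HA1, DDIT4, SFRP1 and HESX1 without SRM array 2 (0.0699 to 0.258).

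Of 13 heat shock genes 3 fell and 0 rose under SRM, with 0 higher and 7 lower when adjusted over the list alone (mean -0.33, camera adjusted p = 7.29e-06, and adjusted p = 0.06 with an estimated correlation). HSPH1 fell by 0.52 ± 0.11, a call lost without KSR control array 1 (0.0524) and without SRM array 2 (0.193). Of 15 genes of the unfolded protein response 5 fell and 1 rose, with 1 higher and 7 lower when adjusted over the list alone. As a list they were lower (mean -0.18, camera adjusted p = 0.0136, and adjusted p = 0.0552 with an estimated correlation). Of 19 p53 targets 3 rose and 0 fell, with 6 higher and 1 lower when adjusted over the list alone (mean 0.28, camera adjusted p = 0.00719, and adjusted p = 0.381 with an estimated correlation). The adjusted p with DMSO as the control was 0.15 for the unfolded protein response list and 0.15 for the p53 list. Of 30 pluripotency genes 1 fell, with 0 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.435), and TERF1 fell by 0.92 ± 0.26, a call lost without KSR control array 1 (0.161), without KSR control array 2 (0.0892), without KSR control array 3 (0.0696), without SRM array 1 (0.104) and without SRM array 2 (0.405). POU5F1 differed by 0.0384 ± 0.12. In all 372 probes were higher and 415 lower, and 30 genes rose and 3 fell at least 2-fold. Limma called 96 without SRM array 2 and 454 without SRM array 1, and 363, 496 and 477 without KSR control arrays 1, 2 and 3. Without each array in turn 16 of 54 named genes kept the call, and 38 lost it without SRM array 2. With DMSO in place of the control 2064 probes passed, among them 486 of the 787 called against the KSR control, and HESX1 differed by 0.26.

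CYM and SRM were compared directly. Doses are not in the labels, so whether they were matched is not known. Across 16564 genes the changes correlated at 0.774, against 0.4 in simulations of unchanged groups with the same controls, and the covariance was 0.0699 against 0.0081. The controls were not divided between the compounds, so sharing them could add to the excess, and pairs of comparisons that share none were also taken. With these shared controls both compounds raised 288 genes and lowered 330, while 1 gene went opposite ways. With SRM set against DMSO, so that no control was shared, the correlation was 0.407 and the covariance 0.0502, against -6.22e-05 in simulations. Both then raised 444 genes, where independent lists would share 104, and lowered 444, where 114 would be shared, while 85 went opposite ways. With CYM set against DMSO instead the correlation was 0.65 and the covariance 0.0623, against -7.52e-05 in simulations. Then 278 genes were raised, 282 lowered and 6 opposite, where 33.8 and 44.2 would be shared. Covariances of this size without a shared control argue against sharing as the main source of the excess.

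Of 13 heat shock genes 7 were lower under CYM than under SRM and 0 higher, with 0 higher and 10 lower when adjusted over the list alone (mean -0.73, camera adjusted p = 5.58e-13, and adjusted p = 0.00625 with an estimated correlation). HSPA8 differed by -1.55 ± 0.15, HSPA1B by -1.66 ± 0.25 and HSPA1A by -1.62 ± 0.23. Of 20 cholesterol synthesis genes 11 were lower under CYM and 0 higher, with 0 higher and 14 lower when adjusted over the list alone (mean -0.47, camera adjusted p = 2.24e-10, and adjusted p = 0.0114 with an estimated correlation). HMGCS1 differed by -1.21 ± 0.14. The list's mean was -0.42 under CYM and 0.0465 under SRM. Higher under CYM were MT1H by 1.93 ± 0.43, NOS3 by 1.72 ± 0.19, CXCL1 by 1.49 ± 0.15 and the cytokine gene IL6 by 1.47 ± 0.28. Of 19 p53 targets 5 were higher, with 11 higher and 0 lower when adjusted over the list alone (mean 0.44, camera adjusted p = 7.33e-07, and adjusted p = 0.076 with an estimated correlation), and GADD45A differed by 1.39 ± 0.23. Calls of the difference were lost for GADD45A, IL6 and MT1H without CYM array 1 (0.0586, 0.203 and 0.308), MT1H without SRM array 1 (0.0647) and MT1H without SRM array 2 (0.0597).

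Of 37 genes named and called under both CYM and SRM, 18 did not pass the test of the difference. CTH differed by 0.0831 (95% interval -0.24 to 0.41), P4HA1 by 0.22 (95% interval -0.0767 to 0.51), DDIT4 by 0.19 (95% interval -0.22 to 0.60) and TAC1 by 0.48 (95% interval -0.12 to 1.08). POU5F1 differed by 0.17 ± 0.13, NANOG by -0.18 ± 0.19 and SOX2 by -0.13 ± 0.14. In all 543 probes were higher under CYM and 621 lower. Limma called 95 without CYM array 1, 259 without SRM array 1 and 733 without SRM array 2, and 16 of 67 named genes kept the call without each array in turn.

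**Figure D3:**
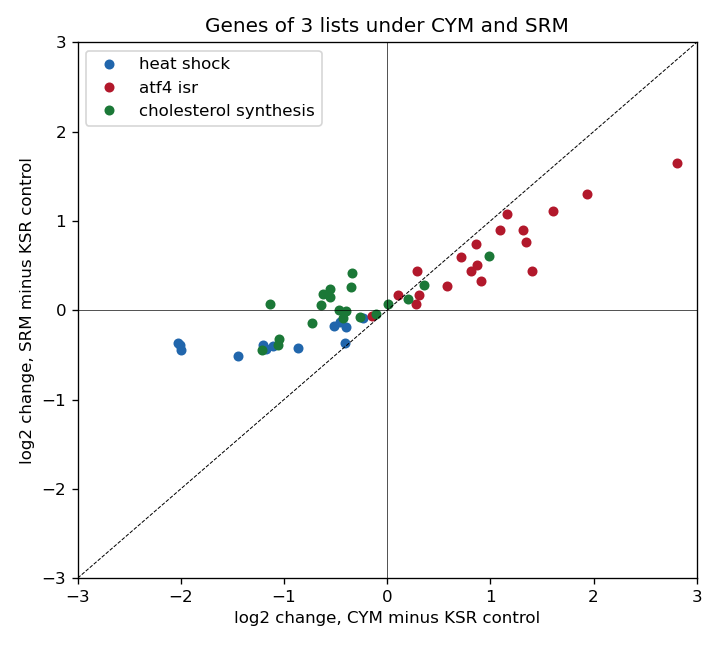
Each point is a gene of the heat shock, amino acid stress (atf4 isr) or cholesterol synthesis list, with its log2 change under CYM on the x axis and under SRM on the y axis, and the dashed line marks equal change. The list means are -1.07 and -0.33 for heat shock, 0.96 and 0.62 for amino acid stress and -0.42 and 0.0465 for cholesterol synthesis.

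DMSO, the solvent group, was compared with the KSR control. The Wnt receptor gene FZD10 rose by 1.75 ± 0.15 (adjusted p = 1.37e-08), the serotonin receptor gene HTR7 by 1.6 ± 0.12 and the Wnt antagonist gene DKK4 by 1.24 ± 0.16. CFAP95 fell by 2.39 ± 0.19, the neuropeptide gene NTS fell by 1.77 ± 0.28 and HESX1 fell by 1.46 ± 0.25. Of 30 pluripotency genes 5 fell and 0 rose, with 0 higher and 10 lower when adjusted over the list alone (mean -0.45, camera adjusted p = 8.7e-08, and adjusted p = 0.25 with an estimated correlation). UTF1 fell by 1.10 ± 0.15, USP44 fell by 0.84 ± 0.18 and GAL fell by 0.84 ± 0.19. Of 11 Wnt targets 4 rose and 0 fell, with 5 higher and 1 lower when adjusted over the list alone (mean 0.32, camera adjusted p = 0.0128, and adjusted p = 0.25 with an estimated correlation), and LEF1 rose by 0.54 ± 0.15. Over the Wnt targets above the median level the mean was 0.10 (adjusted p = 0.926) and camera gave the list as lower. Only 3 of 11 Wnt targets had a mean level above the median of the arrays. Of 38 ribosomal protein genes 5 fell and 0 rose, with 0 higher and 5 lower when adjusted over the list alone (mean -0.12, camera adjusted p = 0.0128, and adjusted p = 0.25 with an estimated correlation), and that list had adjusted p = 0.173 without DMSO array 2. Calls lost, with their adjusted p, were those of NTS, USP44, HESX1 and LEF1 without DMSO array 2 (0.08 to 0.857), GAL without DMSO array 1 (0.222), LEF1 without KSR control array 1 (0.117) and LEF1 without KSR control array 2 (0.116).

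The DMSO arrays differed from one another. They stand after all KSR control arrays in the series, and the labels do not say whether they were processed with them. Against the KSR control, fibroblast-like genes deviated by -0.31 in array 1 and 0.40 in array 2, trophoblast genes by -0.0406 and 0.36, and pluripotency genes by -0.15 and -0.75. In all 370 probes were higher and 553 lower, and 15 genes rose and 52 fell at least 2-fold. Limma called 172 without DMSO array 2 and 1704 without DMSO array 1, and 456 and 578 without KSR control arrays 1 and 2. POU5F1 differed by -0.27 ± 0.12, NANOG by -0.39 ± 0.17 and SOX2 by 0.0581 ± 0.12. Of 65 named genes 15 kept the call without each array in turn, and 48 lost it without DMSO array 2.

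SLG, of the differentiation set, was compared with DMSO. CFAP95 rose by 2.13 ± 0.20 (adjusted p = 2.45e-07), the matrix protein gene HAPLN1 by 1.91 ± 0.44, the interferon-induced gene BST2 by 1.61 ± 0.32, RARRES2 by 1.49 ± 0.16, ZIC2 by 1.42 ± 0.15 and the LIM homeobox gene ISL1 by 1.39 ± 0.28. HTR7 fell by 1.48 ± 0.13, TXNIP fell by 1.27 ± 0.25, FZD10 fell by 1.26 ± 0.16 and DKK4 fell by 1.24 ± 0.18. Of 30 pluripotency genes 3 were higher and 0 lower, with 5 higher and 0 lower when adjusted over the list alone (mean 0.26, camera adjusted p = 0.00016, and adjusted p = 0.347 with an estimated correlation). GAL differed by 1.16 ± 0.21, USP44 by 0.86 ± 0.20 and UTF1 by 0.75 ± 0.16. Without DMSO array 2 that mean was -0.0405 and the adjusted p 0.712, and against the KSR control -0.19 and 0.0519. Trophoblast genes (20 measured, 0 called, 1 higher and 0 lower when adjusted over the list alone) were shifted as a list (mean 0.33, camera adjusted p = 0.00104, and adjusted p = 0.327 with an estimated correlation), with adjusted p = 0.296 without DMSO array 1. Calls lost were those of UTF1, TXNIP, ISL1, BST2, HAPLN1 and USP44 without SLG array 1 (0.0522 to 0.196), TXNIP, USP44, GAL, HAPLN1 and UTF1 without SLG array 2 (0.0667 to 0.212), USP44, GAL, ISL1 and HAPLN1 without DMSO array 1 (0.0693 to 0.395) and USP44, TXNIP and UTF1 without DMSO array 2 (0.0963, 0.109 and 0.317). POU5F1 differed by 0.40 ± 0.13, NANOG by 0.62 ± 0.19 and SOX2 by -0.00675 ± 0.14.

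Cell type lists were higher in both SLG arrays than in the KSR control. Trophoblast genes deviated by 0.44 and 0.53, neural crest genes by 0.34 and 0.44, endoderm genes by 0.29 and 0.32 and fibroblast-like genes by 0.29 and 0.53. Each of these lay above every one of 12 other arrays set against the rest of its own group. The difference between SLG and the KSR control correlated across genes at 0.612 with the deviation of CM_FGF2 array 4, which had no SLG. Against DMSO 145 probes were higher and 99 lower, and 9 of 29 named genes kept the call without each array in turn. Limma called 87 without SLG array 1, 93 without SLG array 2 and 0 with the compared groups alone in the fit. With the KSR control in place of DMSO it called 32, of which 4 were among the 244 called against DMSO, and CFAP95, HTR7 and FZD10 turned to -0.26, 0.12 and 0.49.

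**Figure D4:**
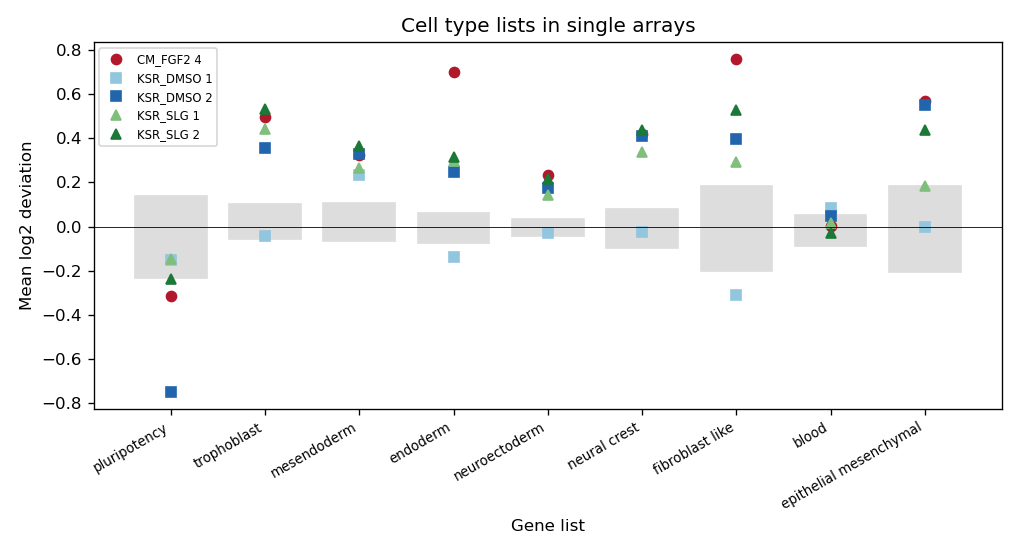
Points give the mean log2 deviation of each list's genes in a single array, for CM_FGF2 array 4 from the other 3 arrays of its group and for the DMSO and SLG arrays from the KSR control mean, and grey boxes the range over 12 other arrays set against the rest of their own groups. CM_FGF2 array 4, DMSO array 2 and both SLG arrays lie above the box for trophoblast, endoderm and fibroblast-like genes.

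RA, CYM and SRM were set beside SLG, with which they share no array. The correlation across genes was -0.0425 for RA, 0.0398 for CYM and 0.0818 for SRM, with jackknife standard errors of 0.107, 0.306 and 0.2. RA correlated at 0.0172 with CYM and 0.0769 with SRM, against 0.4 in simulations of unchanged groups with the shared control, and the covariances were 0.00179 and 0.00453 against 0.00815 and 0.00811.

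**Figure D5:**
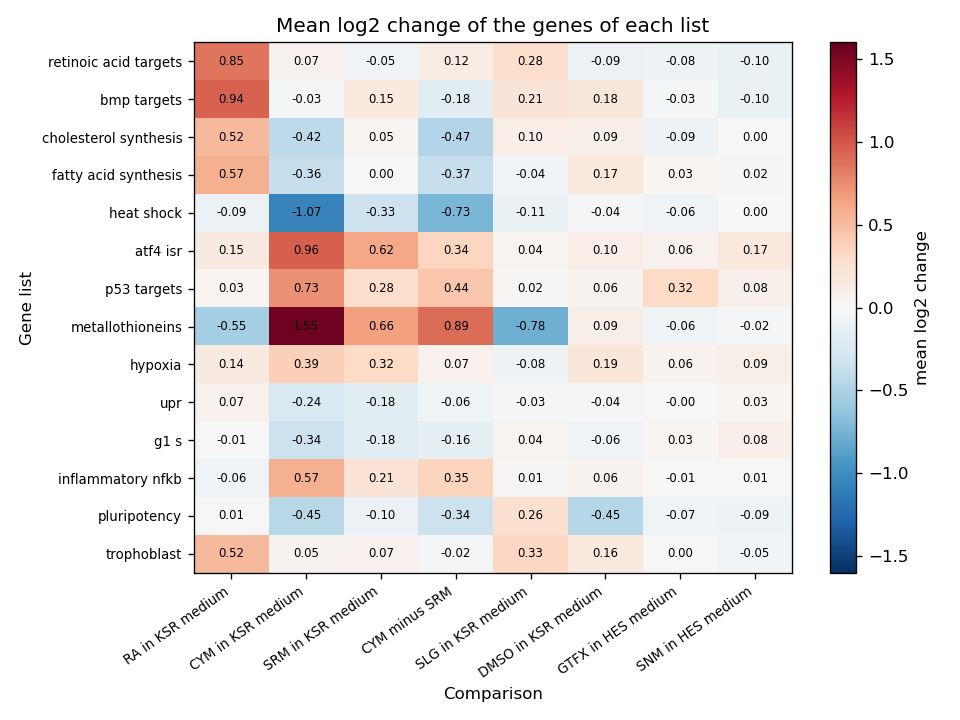
Colours and numbers give the mean log2 change of the genes of 14 lists in 8 comparisons. Heat shock genes have -1.07 under CYM and -0.33 under SRM, and BMP targets 0.94 under RA.

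The control groups of the media were compared. The labels do not say whether a medium already held FGF2 or other factors. In CM medium the growth factor gene NODAL was higher than in HES medium by 1.57 ± 0.30 (adjusted p = 0.00885), FGF8 by 1.43 ± 0.19, FZD10 by 1.44 ± 0.13 and the Notch target gene HEY1 by 1.37 ± 0.17. ANXA1 differed by -2.40 ± 0.48, LRAT by -1.59 ± 0.18 and the fetal liver protein gene AFP by -1.29 ± 0.25. Of 13 NODAL and activin targets 3 were higher and 0 lower, with 5 higher and 0 lower when adjusted over the list alone (mean 0.49, camera adjusted p = 0.00274, and adjusted p = 0.342 with an estimated correlation). Amino acid stress genes (19 measured, 0 called, 0 higher and 5 lower when adjusted over the list alone) were lower as a list (mean -0.29, camera adjusted p = 1.95e-07, and adjusted p = 0.342 with an estimated correlation). POU5F1 differed by 0.0593 ± 0.11, NANOG by 0.46 ± 0.15 and SOX2 by 0.22 ± 0.11. In all 48 probes were higher and 62 lower. Limma called 65 and 38 without HES control arrays 2 and 3, and 58, 48 and 51 without CM control arrays 1, 2 and 3, and 12 of 27 named genes kept the call in turn. Lost were NODAL, AFP and ANXA1 without HES control array 3 (0.0737, 0.088 and 0.136), AFP and ANXA1 without CM control array 1 (0.0882 each) and ANXA1 and NODAL without CM control array 2 (0.0607 and 0.0656).

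In KSR medium the proteasome subunit gene PSMC4 was higher than in HES medium by 0.97 ± 0.18 (adjusted p = 0.0175) and the histone gene H2BC9 by 0.81 ± 0.11. The RNA-binding protein gene IGF2BP2 differed by -0.84 ± 0.18, the surface protein gene PODXL by -0.75 ± 0.15 and SOX4 by -0.70 ± 0.14. Of 30 pluripotency genes 1 was lower, with 0 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0712). Fatty acid synthesis genes (11 measured, 0 called, 0 higher and 3 lower when adjusted over the list alone) were lower as a list (mean -0.19, camera adjusted p = 0.0103, and adjusted p = 0.489 with an estimated correlation), and replication histone genes (14 measured, 0 called, 1 higher and 0 lower when adjusted over the list alone) higher (mean 0.16, camera adjusted p = 0.0103, and adjusted p = 0.395 with an estimated correlation). Without HES control array 2 the adjusted p of these lists was 0.0796 and 0.0796. POU5F1 differed by -0.17 ± 0.11, NANOG by -0.43 ± 0.15 and SOX2 by 0.0341 ± 0.11. Calls lost, with their adjusted p, were those of IGF2BP2, PODXL, PSMC4 and SOX4 without HES control array 2 (0.165 each), SOX4, PSMC4, PODXL and IGF2BP2 without HES control array 3 (0.195 to 0.43), PSMC4, PODXL, IGF2BP2 and SOX4 without KSR control array 1 (0.108 to 0.214), PODXL, PSMC4, SOX4 and IGF2BP2 without KSR control array 3 (0.114 to 0.136) and SOX4, PODXL and IGF2BP2 without KSR control array 2 (0.0603, 0.0838 and 0.109). In all 26 probes were higher and 19 lower, and limma called 470 with the replicate number as a block. It called 265, 1 and 1 without HES control arrays 1, 2 and 3, and 2, 9 and 1 without KSR control arrays 1, 2 and 3.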

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

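The tests of why single arrays stood apart were chosen only after the results were seen, although the fits without single arrays that some of them use, Dixon's ratio, the other splits and the tests of the FGF2 difference between media were fixed before.

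In the FGF2 group of CM medium, array 4 lay far from the other 3 in 7 of 13 results tested with Dixon's ratio. The ratio was 0.889 for FGF and ERK targets, 0.905 for BMP targets, 0.838 for mesendoderm, 0.88 for endoderm, 0.928 for fibroblast-like, 0.886 for NRF2 target genes and 0.924 for epithelial or mesenchymal genes. Besides POU5F1, NANOG, SOX2 and pluripotency genes, the results tested were the lists that passed the preset test for FGF2 in CM medium. None of those passed without array 4, so the usual rate by chance of about 1 in 20 groups does not apply. These lists were also measured on the same 4 arrays and share genes. Array 4 deviated by 0.76 for fibroblast-like, 0.70 for endoderm, 0.49 for trophoblast and 0.42 for neural crest genes, and DMSO array 2 stood apart in the same lists, by 0.40, 0.25, 0.36 and 0.41.

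A candidate explanation is a larger share of other cell types in these cultures. In array 4, 6 of 6 cell type lists lay above the range of 12 other arrays, and 6 of 6 in DMSO array 2. Pluripotency genes lay below that range in both and blood genes within it. Both SLG arrays also lay above it in 6 of 6 lists. The DMSO and SLG arrays were set against the KSR control mean, but the 12 arrays against the rest of their own groups. No group of 2 arrays was in that range. The 2 brightest markers of each list went both ways: of 12, 7 were higher and 5 lower in array 4 than the mean of the other 3 (6 above and 4 below each of them), and in DMSO array 2 8 were higher and 4 lower than the KSR control (7 above and 4 below each control array). TFAP2A was 8.18 in array 4 against 6.11, but EOMES 8.48 against 8.98 and THY1 12.08 against 12.59, so a larger share of all other types alike is not settled. Shared processing stays open as well, since the deviations of the 2 arrays correlated at 0.577 across genes, where the next array reached 0.28. That of array 4 correlated at 0.612 with SLG minus the KSR control, while DMSO array 1 gave -0.0725 with array 4. The series lists its last arrays in the order DMSO array 1, CM_FGF2 array 4, DMSO array 2 and the 2 SLG arrays. The labels do not say whether these were processed apart from the rest. An effect of processing can therefore not be told from one of DMSO or SLG against the KSR control. Whether DMSO array 2 is the whole of the DMSO difference also stays open: 172 probes passed without it, 147 of them among the 923, against 0 with single arrays of THEA or FBP but 319 and 158 with array 2 alone of SNM and GTFX.

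SNM and GTFX differed from the HES control in few probes, and their second arrays deviated together. Array 2 minus array 1 correlated at 0.673 across genes between SNM and GTFX, and the next highest of all pairs of groups was 0.376. A deviation shared by these 2 arrays may therefore lie behind part of both counts and of the correlation between the 2 profiles, and no biological explanation of it was tested. Against it, for the p53 target genes under GTFX, stands the preset test without GTFX array 2 (camera adjusted p = 2.83e-05). With all arrays that list had adjusted p = 0.0641 with an estimated correlation.

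The FGF2 difference between CM and HES medium passed the preset test for 5 lists. The mean difference was 0.281 for endoderm genes (camera adjusted p = 0.0138), 0.138 for amino acid stress genes (0.0308), 0.224 for NRF2 targets (0.0021), -0.101 for genes of G2 and mitosis (0.0393) and 0.221 for epithelial or mesenchymal genes (0.0357). Each had adjusted p = 0.677 with an estimated correlation, and without CM_FGF2 array 4 they had 0.575, 0.575, 0.131, 0.575 and 0.697. Amino acid stress genes also missed the threshold without CM control arrays 1 (0.0501) and 2 (0.113), HES control array 2 (0.128) and HES FGF2 array 2 (0.0586). Genes of G2 and mitosis missed it without HES control arrays 1 (0.107) and 2 (0.09), CM control array 1 (0.144) and HES FGF2 array 3 (0.384). Epithelial or mesenchymal genes missed it without HES FGF2 arrays 1 (0.0609) and 3 (0.0981), HES control arrays 2 (0.0562) and 3 (0.168) and CM control array 1 (0.132).

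Counts were also taken over other splits of the same arrays into groups of the same sizes. A count of 0 is met by every split by construction (35 of 35 for FGF2 in CM medium, 100 of 100 drawn for the FGF2 difference between media and 10 of 10 for FGF2 in HES medium), so these shares say nothing about chance. For FGF2 in CM medium the highest other count was 258, in the split that set arrays 1 and 2 of both groups against the rest, which points to a structure of the samples by replicate number. That split parts none of the 3 pairs of equal number, and no split that parts all 3, as the real one does, called a probe. For the FGF2 difference between media the highest other count, 318, came from a split that again put arrays 1 and 2 of both CM groups together. Groups of 3 against 3 make only 10 splits, too few for a share under 0.05: FGF2 in HES medium gave 0 with a highest other of 0, the CM against the HES control 110 with a highest other of 0 (1 of 10), and the KSR against the HES control 45 with a highest other of 0 (1 of 10).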

How the results depend on the processing

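The alternatives below were chosen before the data were examined, apart from leaving out 4 arrays that stood apart (CM_FGF2 array 4, DMSO array 2, SNM array 2 and GTFX array 2), which was chosen after their correlations were seen. The FGF2, THEA and FBP counts stayed at 0 under every alternative run. Quantile normalization again and centring on medians could change little, since the arrays already shared 1 distribution. They kept all 15 counts within 1.5 times (1170 and 1168 against 1164 for CYM against SRM) and the calls of all 949 named genes. The similarities moved by less than their jackknife standard error in 10 of 10 cases under the block and among genes above the median level, though some near 0 changed sign, such as SNM with FGF2 in CM medium, -0.033 with the block. An intensity floor was not run, since the values are log2, and no signal over background was used, so how far dim genes are limited by it is not known. Where a value moved, the cause was not tested, except where it follows from the design. A 2-fold minimum can only lower a count, and leaving out arrays lowers their number. None of the 4 arrays is in the RA, CYM, SRM, CYM against SRM, CM against HES or KSR against HES comparison. Leaving them out kept every log2 change there, so those counts rose through the shared estimate of the spread.

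With a 2-fold minimum the counts were 0 for SNM, 2 for GTFX, 178 for RA, 569 for CYM, 35 for SRM, 32 for SLG, 76 for DMSO, 106 for CYM against SRM, 22 for CM against HES and 1 for KSR against HES. Array weights gave 1 for SNM, 1317 for SRM, 282 for CM against HES and 638 for KSR against HES. Fits of the compared groups only gave 0 for SNM, 0 for GTFX, 1353 for SRM, 0 for SLG, 254 for DMSO, 539 for CM against HES and 423 for KSR against HES. KSR against HES also moved to 74 among probes above the median level and 29 with a trended and robust eBayes. Without the 4 arrays the counts were 0 for SNM, 3 for GTFX, 1039 for RA, 1390 for SRM, 720 for SLG (174 shared), 371 for DMSO, 1851 for CYM against SRM, 446 for CM against HES and 440 for KSR against HES.

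With the replicate number as a block the counts were 18 for SNM, 53 for GTFX, 541 for SLG, 1541 for DMSO, 330 for CM against HES and 470 for KSR against HES, and no other count left the range of 1.5 times. Of 949 named genes 89 came to pass with the block and 0 lost the call, and of 88 list calls 72 were kept, 15 lost and 1 turned. Where the numbers pair the arrays, in FGF2 in CM medium and KSR against HES, the block changed the 8 list calls and the count given with those comparisons and no other call of a list. For FGF2 in HES medium and CM against HES, where not all pairs correlated above 0.1 (-0.126 to 0.179 and -0.0386 to 0.208), 2 of 3 arrays correlated best with their own number.

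With DMSO as the control the count was 1761 for RA, and 453 of the 663 calls against the KSR control were among them. For SRM it was 2064 (486 of 787) and for CYM 4397 (3056 of 4729). SLG gave 32 against the KSR control (4 shared) and 9 against both. These controls turned named genes: against DMSO, HESX1 0.26, UTF1 0.68, FOXA3 0.26 and RHOBTB3 -0.15 under SRM, and FOXA3 0.22, RHOBTB3 -0.20, TXNRD1 -0.0593 and RPL13 0.00544 under CYM. Of these only UTF1 passed the threshold in its new direction (limma adjusted p = 0.00586). For SLG against the KSR control CFAP95 was -0.26, HTR7 0.12, FZD10 0.49, OPN3 0.17, KLF2 0.0143, UTF1 -0.35, SPRY1 -0.00364 and TXNRD1 0.0896.

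Of 88 list calls, 10 held with an estimated correlation, 81 with the mean of all probes of a gene, 67 among genes above the median level and 70 without the 4 arrays. Lists that turned were epithelial or mesenchymal genes for FGF2 in CM medium (-0.000617 with the block, without the 4 arrays and without CM_FGF2 array 4), HOX genes under RA (-0.0384) and Wnt targets under DMSO (0.0959) among genes above the median level, and, without DMSO array 2, FGF and ERK targets (-0.0222) and immediate early genes (0.035) under DMSO. Wnt and immediate early genes kept a positive mean there, and camera's direction turned. Only 3 of 29 HOX genes and 3 of 11 Wnt targets had a mean level above the median of the arrays. That filter can drop genes raised in few arrays, so these 2 turns say little about them. With DMSO as the control 18 list calls were kept, 14 lost and 3 turned (pluripotency genes under CYM 0.00534, and under SRM FGF and ERK targets -0.0801 and immediate early genes -0.11). For SLG against the KSR control 7 were kept, 1 was lost and pluripotency genes turned (-0.193).

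Leaving out each array in turn gave counts of 0 to 319 for SNM, 1 to 158 for GTFX, 323 to 554 for RA, 2580 to 4183 for CYM, 96 to 496 for SRM, 87 to 294 for SLG, 172 to 1704 for DMSO, 95 to 1416 for CYM against SRM, 38 to 76 for CM against HES and 1 to 265 for KSR against HES, and 0 to 0 for the FGF2, THEA and FBP comparisons. A group left with 1 array is assumed to vary like the others. Among list tests made this way 397 kept the call, 90 lost it and 3 turned. The means of those 3 ranged from -0.000617 to 0.20 for epithelial or mesenchymal genes with FGF2 in CM medium, and under DMSO from -0.0222 to 0.53 for FGF and ERK targets and from 0.035 to 0.51 for immediate early genes.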

Other observations

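The tests of the hypothesis on CYM and SRM, with either control, were chosen after the values were seen, although the fit without CYM array 1 used among them, the gene lists and their tests were fixed before.

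At the preset correlation 3 lists of signalling responses were higher with CYM, while BMP (mean -0.0286), Wnt (-0.15) and retinoic acid targets (0.073) did not pass. Of 24 immediate early genes 8 rose and 0 fell, with 10 higher and 0 lower when adjusted over the list alone (mean 0.39, camera adjusted p = 0.00747, and adjusted p = 0.578 with an estimated correlation). ATF3, a stress transcription factor gene, rose by 1.41 ± 0.22, CCN1 by 1.41 ± 0.22 and KLF6 by 1.59 ± 0.33. Of 13 NODAL and activin targets 4 rose and 0 fell, with 4 higher and 0 lower when adjusted over the list alone (mean 0.41, camera adjusted p = 0.0128, and adjusted p = 0.319 with an estimated correlation), and the activin antagonist gene FST rose by 1.40 ± 0.22. Of 22 FGF and ERK targets 7 rose and 0 fell, with 7 higher and 0 lower when adjusted over the list alone (mean 0.34, camera adjusted p = 0.0465, and adjusted p = 0.606 with an estimated correlation). The phosphatase gene DUSP4 rose by 1.82 ± 0.15, and that list had adjusted p = 0.0867, 0.0624 and 0.087 without KSR control arrays 1 and 3 and CYM array 2. Of 19 extracellular matrix genes 5 rose with CYM and 0 fell, with 5 higher and 0 lower when adjusted over the list alone (mean 0.30, camera adjusted p = 0.0158, and adjusted p = 0.509 with an estimated correlation), and the list had adjusted p = 0.0867 without KSR control array 1 and 0.0733 without CYM array 2. With DMSO as the control the adjusted p under CYM was 0.374 for immediate early genes (mean 0.12), 0.657 for FGF and ERK targets (0.0808), 0.278 for matrix genes (0.16) and 0.0263 for NODAL and activin targets (0.50). Under RA immediate early genes went down as a list, 3 lower and 1 higher of 24 with 1 higher and 5 lower when adjusted over the list alone (mean -0.28, camera adjusted p = 0.00299, and adjusted p = 0.57 with an estimated correlation), and EGR1 fell by 1.38 ± 0.32. The list had adjusted p = 0.323 without RA array 2, and EGR1 lost its call without KSR control array 1 (0.0674), without KSR control array 2 (0.0584) and without RA array 2 (0.376).

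The list of metallothionein genes, whose proteins bind zinc and copper, also holds the zinc transporter gene SLC30A1. Under SRM against the KSR control 1 of 9 members rose and 0 fell, with 2 higher and 0 lower when adjusted over the list alone (mean 0.66, camera adjusted p = 0.00282, and adjusted p = 0.232 with an estimated correlation), and against DMSO the list had adjusted p = 0.132. The member that rose was SLC30A1, by 0.86 ± 0.18, a call lost without KSR control array 1 (0.0568) and without SRM array 2 (0.195). Under SLG against DMSO 0 rose and 0 fell, with 0 higher and 4 lower when adjusted over the list alone (mean -0.78, camera adjusted p = 0.00016, and adjusted p = 0.317 with an estimated correlation), and MT2A differed by -1.35 ± 0.36. Replication histone genes under SLG (14 measured, 0 called, 0 higher and 3 lower when adjusted over the list alone) were lower as a list (mean -0.25, camera adjusted p = 0.00016, and adjusted p = 0.215 with an estimated correlation). Retinoic acid targets under SLG, 2 higher and 0 lower of 22 with 3 higher and 0 lower when adjusted over the list alone, were higher as a list (mean 0.28, camera adjusted p = 0.00104, and adjusted p = 0.327 with an estimated correlation), with adjusted p = 0.207 without DMSO array 1. In CM against HES medium NRF2 targets (12 measured, 0 called, 0 higher and 2 lower when adjusted over the list alone) were lower as a list (mean -0.23, camera adjusted p = 0.00101, and adjusted p = 0.342 with an estimated correlation), and the cystine transporter gene SLC7A11 differed by -0.53 ± 0.13. Cholesterol synthesis genes (20 measured, 0 called, 0 higher and 1 lower when adjusted over the list alone) were lower as well (mean -0.15, camera adjusted p = 0.00274, and adjusted p = 0.342 with an estimated correlation).

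CYM and SRM shared much of their profiles, and a hypothesis is that SRM gave the response to CYM at lower strength. By sign and size alone, heat shock genes are in line with it (mean -0.334 under SRM and -1.07 under CYM), while for cholesterol synthesis genes the mean under SRM was 0.0465, with -0.031 to 0.124 without each array, and -0.0448 with DMSO as the control, so its sign is undecided. The mean under CYM scaled by the slope of SRM on CYM over all genes would be -0.466 for heat shock and -0.183 for cholesterol synthesis genes, and SRM lay above both, with the KSR control or DMSO and without each array in turn. Scaling by this slope (0.437 with the KSR control, 0.567 with DMSO) therefore covers neither list, and other slopes were not tried. The misfit is not particular to them: 7 of the 14 lists called under CYM missed it in this way with the KSR control (3 stronger and 4 weaker in SRM than scaled, amino acid stress genes among the former with 0.621 against 0.42) and 11 with DMSO (1 stronger and 10 weaker, amino acid stress genes not among them). A miss means only that the gap kept its sign without each array, and its size was not tested. Genes of the G1 to S transition, with a gap as small as -0.00908, missed it as stronger with the KSR control but as weaker with DMSO. The difference between the compounds for cholesterol synthesis genes did not rest on CYM array 1, since its camera adjusted p was 1.11e-09 without it.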
